A study of Mus musculus with 6 samples.

How the data were processed

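RNA sequencing libraries (TruSeq RNA kit, Trizol extraction, per the labels) were made from 2 mouse pre-iPSC lines, pre2-2 and pre3. Pre-iPSCs are partially reprogrammed cells. Here they came from fibroblasts of OG2 mice, which carry a GFP reporter driven by the Pou5f1 promoter. Each line, at passage 10, was left untransfected, transfected with a control siRNA or transfected with an siRNA against Tet1, and kept in mouse embryonic stem cell medium with LIF and 50 µg/ml vitamin C. Each of the 6 combinations gave 1 library, so each treatment had 2 libraries, replicate 1 from pre2-2 and replicate 2 from pre3. The labels differ on times: the series description puts vitamin C 16 h after transfection and RNA extraction 32 h later, whereas the sample descriptions give 48 h from transfection to RNA with 36 h of vitamin C. The labels also call the treatment Tet siRNA in a characteristic and Tet1 siRNA in the title and description; it was taken as Tet1. The source name and cell type read MEFs, that is fibroblasts, while the series description names pre-iPSCs, and the samples were taken as the latter. They do not say whether the libraries of a line came from separately grown cultures.

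Each deposited file gave, per gene symbol, an expected count and a fraction; the authors made both with RSEM 1.1.21 on mm9, per the labels. The expected count is RSEM's estimate of the number of reads from a gene, with no normalization, and 18.7 to 21.4% of the values per library were not whole at a tolerance of 0.005. The fraction, as deposited, is the estimated share of transcripts from a gene, which sums to 1 per library and gives TPM on scaling. Read length, aligner settings and filters are not stated. The files list 20325 genes by symbol with RefSeq transcripts and give no positions; the reference at hand was a later mouse build than mm9, so no coordinates are given. A table of TPM for the whole series was left out because it repeats the fractions and a column name in it names Tet2, which matches no sample.

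Library totals were 1868640 to 2582800 expected counts. A floor of 3 counts corresponded to 1.16 to 1.61 CPM across libraries; floors and counting intervals cover counting error only, since the files hold no molecular identifiers, while bootstrap intervals cover the spread between genes. CPM values are given with TMM scaling, whose factors were 0.982 to 1.01. Using edgeR's relative log expression (RLE) factors or library totals alone moved the median log2 difference between libraries by at most 0.0387.

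Expected counts were rounded and tested with edgeR 4.0.16 (R 4.3.3): TMM, filterByExpr by treatment with a minimum count of 10, which kept 11048 genes, and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The model held cell line and treatment and was fitted to all 6 libraries, which share an estimate of spread (common dispersion 0.00755, prior degrees of freedom 23.2, residual degrees of freedom 2). Standard errors were computed as the absolute log2 fold change over the square root of F. The comparisons were siTet1 vs control siRNA, control siRNA vs untransfected, siTet1 vs untransfected, pre3 vs pre2-2, and the interaction of line with siTet1 or not. The interaction model held the line, siTet1 or not and their product, with the control siRNA and untransfected libraries of a line pooled as its 2 controls (residual degrees of freedom 2); it assumes that these vary like replicates. Every adjusted p given for a gene comes from edgeR unless DESeq2 1.42.0 or limma 3.58.1 is named. All p-values of treatments rest on 2 lines with 1 library each; with 2 libraries against 2 an exact permutation test cannot go below 0.333. Where a group had 0 counts in every library, the fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, it is given as the ratio of summed counts, scaled by the library totals, with an exact 95% counting interval.

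The cell line was checked as a term of the model. Expression in log2 CPM correlated across genes at 0.953 to 0.975 between libraries of the same line and at 0.883 to 0.938 between lines, so libraries of a line resembled each other more. With the line as the replicate block and only the 4 libraries of siTet1 and control siRNA, 614 genes were called between them.

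The 24 gene lists were pluripotency network, epithelial, mesenchymal transition, fibroblast and matrix, DNA methylation and demethylation (without Tet1), jumonji histone demethylases, collagen and HIF hydroxylases, interferon and double-stranded RNA response, germline, trophectoderm, Nodal and TGF-beta targets, BMP targets, mesoderm and endoderm, neural, Hox, mitosis, DNA replication, p53 targets and senescence, ATF4 and unfolded protein response, glycolysis and hypoxia, cholesterol synthesis, imprinted, haematopoietic and endothelial, and muscle and fat. They hold 574 entries, of which 567 were in the files; 5 were found through synonyms, and Col6a3, Hmgcs1, H19, Meg3, Rian, Mirg and Airn were not analysed here. Each list was tested with limma's camera with a preset correlation of 0.01, adjusted over the 24 lists of a comparison, and again with an estimated correlation. The second form rests on the 2 residual degrees of freedom of the fit. A call lost there therefore does not show that correlation between genes was the reason. Members were also counted with p adjusted over the list alone. The test, the lists, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined, except for a comparison of the transfection response between lines, which was added later. Single genes named are Tet1, Tet2, Tet3, Nanog, Pou5f1, Sox2, Cdh1, Epcam, Snai1 and Vim. To these come the 12 most raised and the 12 most lowered genes of each treatment comparison (10 and 10 between lines) among called genes with an average log2 CPM of at least 1 and the same sign in both lines, and up to 4 members with the lowest p of each list that was called or had called members. Without 5 called genes, the 5 with the lowest p were taken. Of unnamed loci that met the rule, 3 (Gm906, E130309F12Rik and 2010001M09Rik) are not described. A further 5 genes that met the rule are not reported here.

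The procedure was tested on simulated data with 200 changed genes among 11048. For siTet1 vs control siRNA it recovered 32.8% of 1.5-fold, 64.2% of 2-fold and 87.9% of 4-fold changes, with 2 false calls among 125. For the interaction of line and siTet1 the recovered shares were 5.97%, 22.4% and 72.7%, with 1 false call among 68. A simulated shifted list of 25 genes gave a camera p of 8.94e-23 and an unshifted list 0.614. Genes were simulated independently, so these values do not show how camera behaves where the genes of a list are correlated. To find genes whose reads cannot be assigned with certainty, 50-base words were compared between reference transcripts: of 221 named genes, 212 were found there and 11 shared over 10% of their words with a second gene. Named genes not found there could not be checked in this way.

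Alternatives tried were edgeR's RLE factors, library totals alone, no filter, a filter at 2 CPM in 4 libraries, a minimum absolute log2 fold change of 1, DESeq2's test, limma on log2(TPM + 1), counts not rounded, no cell line in the model, only the 4 libraries compared, both control groups pooled, no treatment term for the lines, and leaving out each library in turn. In the last case the remaining library of a group is assumed to vary like the other groups.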

Results

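Messenger RNA was sequenced from 2 partially reprogrammed mouse lines, pre2-2 and pre3, each left untransfected, given a control siRNA or given an siRNA against Tet1, a dioxygenase that oxidises 5-methylcytosine. Each of the 6 combinations gave 1 library. In pre2-2 the untransfected, control siRNA and siTet1 libraries held 2582800, 1975140 and 2141340 expected counts. In pre3 they held 1992130, 1886490 and 1868640. Between 13506 and 14128 genes had a count in a library, and the 10 most abundant genes took 4.28 to 5.36% of the counts. The first principal component held 62.6% of the variance and separated the lines; the second held 14.9% and the third 9.64%. On the first, the untransfected pre2-2 library lay at -19.0, apart from the control siRNA (-41.5) and siTet1 (-41.2) libraries of its line. In pre3 the untransfected library lay at 43.4, also above the control siRNA (32.2) and siTet1 (26.1) libraries. On the second, the siTet1 libraries lay at -21.8 and -20.5, the untransfected pre2-2 library at 28.1 and the other 3 at 4.62 to 4.82. Fold changes are log2 values with the SE from the fit to all 6 libraries (2 per treatment), and levels are CPM, counts relative to the TMM-scaled library total.

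Tet1 was at 250 CPM in untransfected pre2-2, 246 with control siRNA and 154 with siTet1, and at 205, 251 and 159 CPM in pre3 in the same order. With siTet1 it fell by 0.67 against control siRNA (SE 0.13, 0.629-fold, adjusted p = 0.0043) and by 0.54 against untransfected cells (SE 0.13, adjusted p = 0.00951), while control siRNA differed from untransfected by 0.13 (adjusted p = 0.871). The related Tet2 differed by -0.24 (adjusted p = 0.621) and Tet3 by 0.23 (adjusted p = 0.651) between siTet1 and control siRNA, and neither was called. The size of the Tet1 change ran from -0.76 to -0.58 when each library was left out, and its call ended without the pre2-2 siTet1 library (-0.58, adjusted p = 0.307) or the pre3 control siRNA library (-0.59, adjusted p = 0.191). It also ended with DESeq2 (adjusted p = 0.103), with limma (adjusted p = 0.248) and without the cell line in the model (adjusted p = 1.00). Against untransfected cells it ended without the pre2-2 untransfected library (-0.37) and without the pre2-2 siTet1 library (-0.45).

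**Figure D1:**
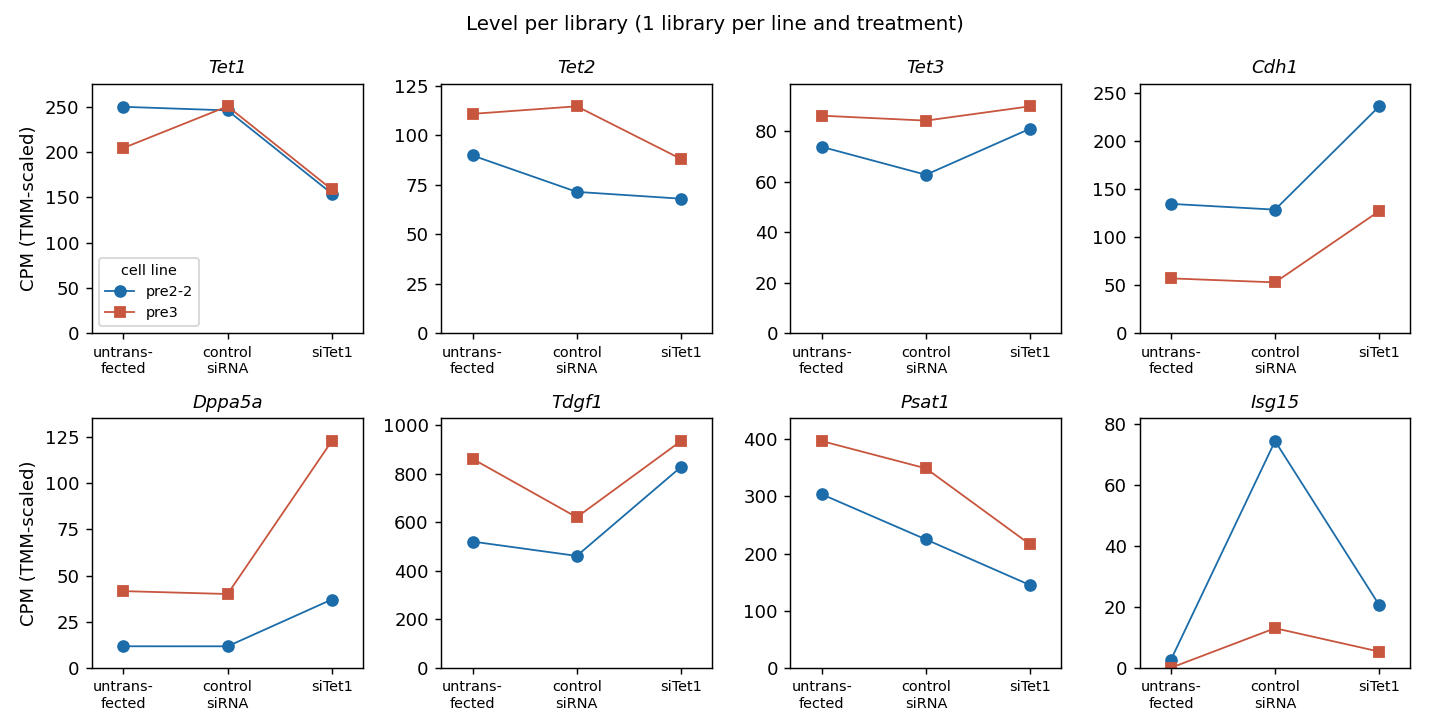
CPM (linear axes from 0) in each of the 6 libraries for Tet1, Tet2, Tet3, Cdh1, Dppa5a, Tdgf1, Psat1 and Isg15, by treatment, with a point per library coloured by line. Tet1 lies at 154 and 159 CPM with siTet1 and at 205 to 251 CPM in the other libraries, and Isg15 is highest with control siRNA in both lines.

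The question of siTet1 against control siRNA was which genes change when Tet1 is reduced in pre-iPSCs kept in vitamin C. Cdh1, which encodes E-cadherin, the adhesion protein of epithelial and pluripotent cells, was 1.04 higher with siTet1 (SE 0.14, adjusted p = 0.000133; 129 to 236 CPM in pre2-2 and 52.8 to 127 in pre3). Dppa5a, a gene of pluripotent cells, was 1.63 higher (SE 0.20, adjusted p = 1.92e-05; 11.6 to 37.0 and 40.0 to 123 CPM), and shares 12.3% of its 50-base words with Pigp. Aldh1a3, a retinoic acid synthesis enzyme, was 3.28 higher (SE 0.52, adjusted p = 0.000586) and the placental homeobox gene Rhox6, which shares 16.5% of its words with Rhox9, was 3.10 higher (SE 0.46, adjusted p = 0.000306). Of 29 interferon response genes, 16 were lower with siTet1 than with control siRNA, and the call of the list ended with an estimated correlation (adjusted p = 0.441). Among them was Irf7, by which the response amplifies itself, which fell by 1.99 (SE 0.29, adjusted p = 0.000305).

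In all, edgeR's quasi-likelihood test called 175 of 11048 genes, 127 higher and 48 lower with siTet1, of which 89 changed at least 2-fold and 171 had the same direction in both lines. The model holds a single treatment effect for both lines, so the call itself favours genes with the same direction. The number with the same direction is therefore no check of agreement, here or in the other comparisons. Without adjustment, 1196 genes had a p under 0.05, where 552.4 would be expected by chance. The count was 24 with DESeq2, 33 with limma, 114 with both control groups pooled, 89 at a log2 change of at least 1 and 292 without a filter. It was 614 from the 4 libraries compared with the line as replicate block, and 0 without the line in the model, where 178 genes had an unadjusted p under 0.05. Without the pre2-2 siTet1 library 32 genes were called, 76 without the pre2-2 control siRNA library and 111 without that of pre3. Without the untransfected library of pre2-2 or of pre3 the count was 625 and 618. Of the 39 named genes called, 7 were called without each library in turn: Cdh1 (0.88 to 1.26), Dppa5a (1.62 to 1.68), Aldh1a3, Rhox6, the matrix gene Tnc (0.69 to 0.92), Gm4535 and Rangrf. Rhox6 was at 4.91 without the pre3 siTet1 library, and the pre2-2 control siRNA library had no counts of it. Gm4535 and Rangrf share reads with each other and are treated with the control siRNA effect; both lost their call with pooled controls, and Tnc lost its call with limma. Cdh1, Dppa5a, Aldh1a3 and Rhox6 also passed under every other setting that kept the line.

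Among the most raised genes, Raet1c, a ligand of the natural killer cell receptor NKG2D, had no counts in either control siRNA library and 18.7 and 5.79 CPM with siTet1, at least 16.4-fold higher. It had no counts in the untransfected libraries either. Such all-or-none levels also occurred in genes with shared reads, and no summed count of Raet1c with another gene was tested. Robo4, a receptor of endothelial cells, was 2.61 higher (SE 0.48, adjusted p = 0.00271), Fam167a 2.74, Ccnjl 2.39, Rdh16 2.26, Slc12a3 2.25, Prg4 2.03 and Mall 2.02 higher. Peg10, an imprinted gene needed for the placenta, was 1.49 higher (SE 0.18, adjusted p = 1.63e-05; 144 to 451 CPM in pre2-2 and 11.2 to 17.6 in pre3). Among genes lowered, Tph1, an enzyme of serotonin synthesis, fell by 3.17 and the homeobox gene Tlx3 by 1.99. Each of these calls ended without the pre2-2 siTet1 library. There Robo4 was at 2.84, Fam167a 2.61, Ccnjl 1.62, Rdh16 2.19, Slc12a3 1.99, Prg4 2.02 and Mall 1.28. Peg10 was at 0.83 and Tlx3 at -1.49, and Raet1c had an adjusted p of 0.55. All but Robo4 also ended without the pre2-2 control siRNA library, where Peg10 was at 0.66, Mall at 1.15 and Rdh16 at 1.31. Slc12a3 (2.13), Prg4 (1.76) and Tlx3 (-2.16) were not called without the pre3 control siRNA library, nor Rdh16 (2.32) and Prg4 (2.04) without the pre3 siTet1 library.

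Of the 29 interferon and double-stranded RNA response genes tested, 16 were lower with siTet1 than with control siRNA and none higher (0 and 27 adjusted over the list alone), and all 29 had a negative fold change. The list median was -1.12, with -1.50 in pre2-2 and -0.43 in pre3 (camera adjusted p = 1.72e-42). With an estimated correlation the adjusted p was 0.441. Irgm1, an immunity GTPase, fell by 1.96 (SE 0.22, adjusted p = 6.25e-06; 199 to 48.1 CPM in pre2-2 and 18.6 to 6.77 in pre3). Isg15, a ubiquitin-like modifier, fell by 1.71 (SE 0.28; 74.5 to 20.6 and 13 to 5.32 CPM), Oasl2 by 1.87, Usp18 by 2.02 and Gbp3 by 2.56. Iigp1, with 1 count against 26, was 27.0-fold lower (95% counting interval 4.44 to 1107). Apol9a (-3.09), Tgtp1 (-3.01) and Irgm2 (-2.16), outside the list, also fell. Tgtp1 shares 79.4% of its 50-base words with Tgtp2. The calls of the genes named here ended without the pre2-2 siTet1 library. There Irf7 was at -1.52, Isg15 -1.20, Oasl2 -1.12 and Irgm1 -1.19. The siTet1 library left held 3 counts or fewer of Usp18, Gbp3, Iigp1, Apol9a, Tgtp1 and Irgm2, the last with the opposite sign (0.15). Except for Irgm1 they also ended without the pre2-2 control siRNA library. There Irf7 was at -1.74, Isg15 -1.43, Oasl2 -1.40, Usp18 -1.62, Apol9a -2.69 and Tgtp1 -4.74.

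Of 20 epithelial genes tested, 2 were higher (Cdh1 and the keratin Krt19, 0.72) and none lower, with 3 higher adjusted over the list alone and a median of 0.30 (camera adjusted p = 0.000104, and adjusted p = 0.441 with an estimated correlation). Perp, an adhesion gene that passed over the list alone, stood at 0.33 (adjusted p = 0.12), Cdh3 at 1.23 (adjusted p = 0.237) and Epcam at 0.30 (adjusted p = 0.555). Of 24 pluripotency network genes, 2 were higher, Dppa5a and the Nodal co-receptor Tdgf1 (0.72, SE 0.11, adjusted p = 0.000542), with the same 2 counted over the list alone and a median of 0.15 (camera adjusted p = 0.000603, and adjusted p = 0.441 with an estimated correlation). The reprogramming factors Pou5f1 (0.10, adjusted p = 0.671) and Sox2 (0.17, adjusted p = 0.614) were not called, and Nanog, at 0 to 3.61 CPM, was too low to be tested. Of 7 trophectoderm genes, 2 were higher, Rhox6 and Peg10, with 3 higher over the list alone and a median of 0.41 (camera adjusted p = 2.16e-06, and adjusted p = 0.441 with an estimated correlation). The pluripotency list lost its call without the pre2-2 control siRNA library (adjusted p = 0.0779). The call of Krt19 ended without that library (0.62) or the pre2-2 siTet1 library (0.37), and that of Tdgf1 without the latter (0.52).

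Mitosis genes were lower as a list, with a median of -0.27 (camera adjusted p = 2.19e-09, and adjusted p = 0.708 with an estimated correlation). None of 25 was called over all genes and 2 passed over the list alone (Mki67, -0.36, and Ube2c). All but 1 had a negative fold change. DNA replication genes, 0 of 25 called, had a median of -0.12 (camera adjusted p = 0.00285, and adjusted p = 0.833 with an estimated correlation). The list lost its call without the pre2-2 siTet1 library (adjusted p = 0.375) or the pre3 control siRNA library (adjusted p = 0.162). The 6 mesoderm and endoderm genes, with 0 called and Evx1 alone (1.68) passing over the list, had a median of 0.73 (camera adjusted p = 0.00942, and adjusted p = 0.441 with an estimated correlation). Without the line that p was 0.0538, and without the pre3 siTet1 library 0.175. The 2 germline genes tested, with 0 called over all genes and 1 lower over the list alone, had a median of -1.03 and Tex19.1 stood at -1.51 (camera adjusted p = 0.0394, and adjusted p = 0.580 with an estimated correlation). The germline call ended without either untransfected library (0.0706 for pre2-2 and 0.0666 for pre3), the pre3 control siRNA library (0.162) or either siTet1 library (0.0841 and 0.0882).

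Other lists were not called between siTet1 and control siRNA. In the mesenchymal transition list (camera adjusted p = 0.181) 1 of 27 genes was higher, Tnc (0.80, SE 0.11, adjusted p = 0.000136). The matrix gene Thbs1 was lower (-0.70; no call at -0.40 without the pre2-2 control siRNA library), and over the list alone 4 were higher and 1 lower. Snai1 stood at 0.02 and Vim at 0.15. In the fibroblast and matrix list (0.760) Col3a1 was higher (0.54; no call at 0.30 without the pre3 control siRNA library, 0.59 without the pre2-2 and 0.50 without the pre3 siTet1 library). The list was called lower without the pre3 control siRNA library (0.00366) and higher without that of pre2-2 (0.00051). Psat1, a serine synthesis enzyme of the ATF4 and unfolded protein response list (0.0542), fell by 0.67 (SE 0.12, adjusted p = 0.00256), with no call without the pre2-2 siTet1 library (-0.63) or the pre3 control siRNA library (-0.58). The imprinted list (0.760; median 0.04, mean -0.01, test direction up) held Igf2, 0.58 higher, and the p53 targets and senescence list (0.760) the death receptor gene Eda2r (-0.53). Single called genes were also in the Nodal and TGF-beta list (0.181), Tdgf1, and in the muscle and fat list (0.235), Acta1, 1.90 higher. The calls of Igf2, Eda2r and Acta1 ended without the pre2-2 siTet1 library (0.48, -0.48 and 0.48) and without the pre2-2 control siRNA library (0.72, -0.54 and -0.12, the last of the opposite sign). Those of Igf2 (0.48) and Eda2r (-0.52) ended without the pre3 control siRNA library too, and Eda2r without the pre3 siTet1 library (-0.60). No member was called over all genes in the lists of DNA methylation and demethylation, which does not hold Tet1 (camera adjusted p = 0.890), jumonji histone demethylases (0.958), collagen and HIF hydroxylases (0.623) and BMP targets (0.610). The same held for neural genes (0.976; median -0.03, mean 0.04, test direction down), Hox (0.610), glycolysis and hypoxia (0.177), cholesterol synthesis (0.187) and haematopoietic and endothelial genes (0.833). Some of these lists gained a call, in the direction of the main test, when a library was left out. The mesenchymal list was called without the untransfected library of pre2-2 (0.0452) or pre3 (0.0462), the pre2-2 control siRNA library (0.00535) or the pre3 siTet1 library (0.00194). The Nodal (0.0448 and 0.0462), ATF4 (0.0342 and 0.0374) and glycolysis lists (0.0448 and 0.0462) were called without the untransfected library of pre2-2 or pre3, and the glycolysis list also without the pre2-2 siTet1 library (0.00143). The muscle and fat list was called without the pre3 control siRNA (0.0256) or siTet1 library (0.0243), cholesterol synthesis without the former (0.0493) and hydroxylases without the latter (0.0491).

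**Figure D2:**
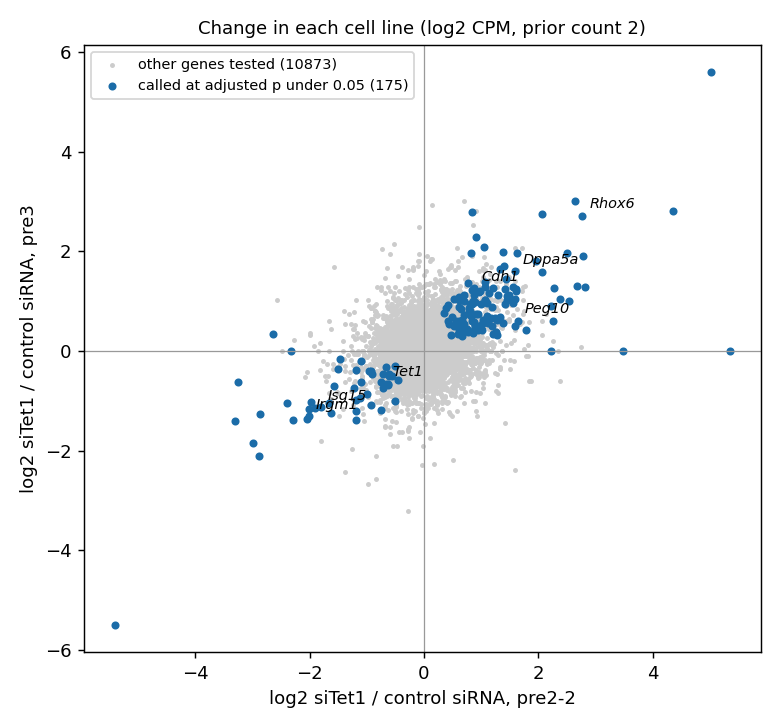
Log2 siTet1 over control siRNA in pre2-2 (horizontal) and pre3 (vertical), with a point per gene tested, 175 called genes in blue and the others in grey. Most called genes lie in the quadrants where both lines have the same sign, 171 of 175. The model holds a single treatment effect for both lines, so the call itself favours such genes.

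Across the 11048 genes the siTet1 minus control siRNA differences of the 2 lines correlated with a Pearson r of 0.339 and a Spearman rho of 0.273; genes are not independent replicates, so no p is given. Among the 10123 genes with an average log2 CPM of at least 3, r was 0.374. For control siRNA minus untransfected, r was 0.233 and rho 0.0905.

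Control siRNA against untransfected cells was compared as a background of transfection, though a state of the untransfected pre2-2 culture could enter it too. Of 29 interferon response genes 21 were higher, and the call of the list ended with an estimated correlation (adjusted p = 0.552). Irf7 was 5.05 higher (SE 0.42, adjusted p = 7.44e-09) and Isg15 4.89 higher (SE 0.40, adjusted p = 7.44e-09; 2.60 to 74.5 CPM in pre2-2 and 0 to 13 in pre3). Oas2, a sensor of double-stranded RNA, was 4.42 higher (SE 0.23, adjusted p = 1.67e-12; 9.71 to 182 and 2.05 to 73.6 CPM). Of 25 genes of fibroblasts and extracellular matrix 13 were higher, and the call of this list also ended with an estimated correlation (adjusted p = 0.552). Among them were the collagen gene Col1a1 (752 to 2054 CPM in pre2-2 and 367 to 480 in pre3) and the collagen cross-linking enzyme Lox (59.8 to 227 and 23.6 to 33.6 CPM). The glycolytic enzymes Ldha (-0.37), Eno1 (-0.37) and Pfkp (-0.54) were lower.

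The test called 164 genes, 153 higher and 11 lower, of which 112 changed at least 2-fold and 155 had the same direction in both lines; 1016 had an unadjusted p under 0.05. The count was 32 with DESeq2, 32 with limma, 259 without a filter, and 0 without the line in the model, where 84 genes had an unadjusted p under 0.05. It was 29 without the pre2-2 control siRNA library and 713 without the pre3 untransfected library. Without the pre2-2 untransfected library it was 113, of which 46.0% were higher and 41 were among the 164. Of the 33 named genes called, 10 were called without each library: Usp18 (93 counts against 2, 55.1-fold, 95% counting interval 14.8 to 462), Irf7, Isg15, Oasl2 (4.57), Oas2, Ifi27l1 (4.35, SE 0.31, adjusted p = 4.83e-10), Thbs1, Rangrf, Gm4535 and Amd1. The pre3 untransfected library had no counts of Usp18, Irf7, Isg15 and Oasl2.

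Of the 29 interferon genes tested, 21 were higher with control siRNA and none lower, with 25 higher and 1 lower (Irf1, -0.74) over the list alone. The median was 1.35, also with Rtp4 set at its bound, with 1.42 in pre2-2 and 1.06 in pre3 (camera adjusted p = 9.04e-79, and adjusted p = 0.552 with an estimated correlation). Rtp4 had no counts in either untransfected library and was at least 27.6-fold higher; its call ended without the pre2-2 untransfected (adjusted p = 0.072) or control siRNA library (adjusted p = 0.13). The RNA-binding antiviral gene Ifit1 (110 counts against 3) was 43.4-fold higher (95% counting interval 14.5 to 214) and Ifi44 (57 against 2) 33.8-fold higher (8.93 to 286). Both calls ended without the pre2-2 untransfected library or the pre2-2 control siRNA library. Apol9a (91 counts against 2) was 53.9-fold higher (14.5 to 452), with no call without the pre2-2 control siRNA library. Apol9b (52 against 2) was 30.8-fold higher (8.11 to 261), with no call without the pre2-2 untransfected library. The 2 share 16.5 and 52.3% of their 50-base words with each other.

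Of 25 fibroblast and matrix genes, 13 were higher and none lower (17 and 0 over the list alone). The median was 0.81, with 1.06 in pre2-2 and 0.13 in pre3 (camera adjusted p = 2.19e-22, and adjusted p = 0.552 with an estimated correlation). The list kept its direction and call without each library in turn, that of untransfected pre2-2 included. Lox was 1.51 higher (SE 0.22, adjusted p = 9.93e-05), the smooth muscle gene Tagln 1.16 higher (SE 0.18), Col5a1 0.98 higher (SE 0.14) and Col1a1 0.94 higher (SE 0.14). Of 27 mesenchymal transition genes, 4 were higher and none lower (15 and 0 over the list alone), among them Thbs1 (1.65, SE 0.15, adjusted p = 3.47e-08), Itga5 (0.69) and Tnc (0.57). The list median was 0.47, with 0.75 in pre2-2 and 0.04 in pre3 (camera adjusted p = 1.24e-12, and adjusted p = 0.552 with an estimated correlation). Without the pre2-2 untransfected library the mesenchymal list was no longer called (adjusted p = 0.328), and neither were Lox (0.55), Tagln (0.46), Itga5 (0.18) and Tnc (0.33). Without the pre2-2 control siRNA library, Lox (0.99), Tagln (0.69), Col5a1 (0.76), Col1a1 (0.57), Itga5 (0.38) and Tnc (0.45) were not called.

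Of 22 glycolysis and hypoxia genes, 3 were lower and none higher (9 and 0 over the list alone), with a median of -0.25 (camera adjusted p = 9.66e-09, and adjusted p = 0.552 with an estimated correlation). Ldha went from 1494 to 1159 CPM in pre2-2 and from 2548 to 1958 in pre3 (-0.37, SE 0.08, adjusted p = 0.0152). The 3 calls ended without either control siRNA library, where Ldha was at -0.38 and -0.36, Eno1 at -0.37 and -0.38, and Pfkp at -0.51 and -0.58 for pre2-2 and pre3. Eno1 was also not called without the pre2-2 untransfected library (-0.28), nor Pfkp without the pre3 untransfected library (-0.38). Of other lowered genes, the hearing gene Pdzd7 fell by 1.15, Acsbg1 by 0.75, Fxyd6 by 0.67, Nlrp1a by 0.59 and Crabp2, a retinoic acid carrier, by 0.59. These calls ended without the pre2-2 control siRNA library (-1.08, -0.64, -0.71, -0.47 and -0.62) or that of pre3 (-1.19, -0.91, -0.61, -0.73 and -0.53). Crabp2 was at -0.18 without the pre3 untransfected library. Pdzd7 (-1.13) and Nlrp1a (-0.43) were also not called without the pre2-2 untransfected library.

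Mitosis genes, with 0 of 25 called, had a median of -0.15 (camera adjusted p = 0.00171, and adjusted p = 0.671 with an estimated correlation) and DNA replication genes, with 0 of 25 called, -0.13 (camera adjusted p = 0.0104, and adjusted p = 0.636 with an estimated correlation). Without the pre2-2 untransfected library both lists turned to the other direction (adjusted p = 0.958 and 0.869), and without the pre2-2 control siRNA library they were not called (0.235 and 0.343). The mesoderm and endoderm list (0 of 6 called, median 0.50, camera adjusted p = 0.0353, and adjusted p = 0.552 with an estimated correlation) lost its call without the line (0.196) and without the pre2-2 untransfected (0.134), pre2-2 control siRNA (0.277) or pre3 untransfected library (0.131). The imprinted list (0 of 18 called, median 0.23, camera adjusted p = 0.0484, and adjusted p = 0.615 with an estimated correlation) lost it without the line (0.185) and without the pre2-2 untransfected (0.608), pre2-2 control siRNA (0.459), pre2-2 siTet1 (0.059) or pre3 siTet1 library (0.0584).

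Lists not called held 3 single called genes. Peg10 among trophectoderm genes was 1.62 higher (camera adjusted p = 0.887; list median -0.25, mean 0.02). Gadd45g in the DNA methylation list (0.146) was 1.51 higher and Fst in the Nodal and TGF-beta list (0.887) 1.12 higher. These calls ended without the pre2-2 untransfected library (1.82, 1.20 and 0.59), and those of Gadd45g (0.34) and Fst (1.09) also without the pre2-2 control siRNA library. No member was called over all genes in the pluripotency (0.0586), epithelial (0.146), jumonji (0.142) and hydroxylase lists (0.915; median 0.05, mean 0.07, test direction down). Nor was any in the germline (0.228), BMP (0.106), neural (0.589), Hox (0.734; median -0.08, mean 0.01), p53 (0.589), ATF4 (0.217), cholesterol (0.915; median 0.03, mean -0.00, test direction down), haematopoietic and endothelial (0.209) and muscle and fat (0.300) lists. Of these, the pluripotency (0.0197 and 0.0179) and BMP lists (0.0276 and 0.00634) gained a call, in the direction of the main test, without the pre3 untransfected or control siRNA library. The haematopoietic and endothelial list gained it without the pre3 control siRNA library (0.0179) and the epithelial list without that of pre2-2 (0.0284).

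The largest fitted changes belonged to genes whose reads are shared. Rangrf was at least 62.8-fold higher, Gm4535 at least 61.9-fold lower and Amd1 at least 189-fold lower with control siRNA than in untransfected cells. Against control siRNA, siTet1 cells had Gm4535 at least 48.5-fold higher and Rangrf at least 55.0-fold lower. Rangrf and Gm4535 share 21.3 and 58.5% of their 50-base words with each other, and Amd1 shares 76.7% with Amd2. The summed counts of Rangrf and Gm4535 were 30.4 to 49.7 CPM across libraries and those of Amd1 and Amd2 199 to 256 CPM, both without TMM scaling. The sums were not called for control siRNA against untransfected (-0.25, adjusted p = 0.796, and -0.07, adjusted p = 0.938). The Amd1 call ended with DESeq2.

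**Figure D3:**
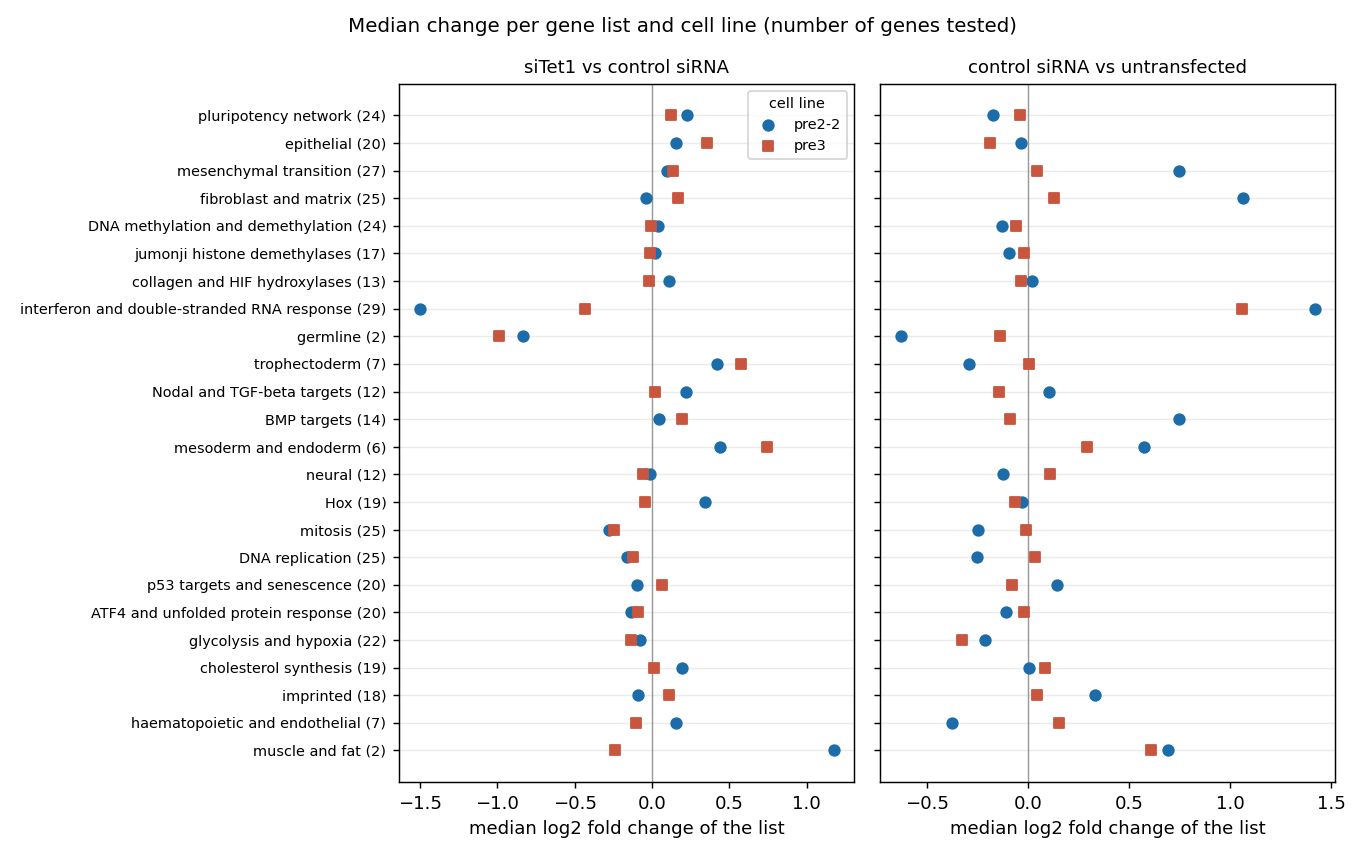
Median log2 fold change of each of the 24 gene lists in pre2-2 and in pre3 (a point per line), for siTet1 against control siRNA and for control siRNA against untransfected. The interferon list lies at 1.42 and 1.06 for control siRNA and at -1.50 and -0.43 for siTet1 against control siRNA, and the fibroblast and matrix list at 1.06 and 0.13 for control siRNA.

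SiTet1 against untransfected cells combined both steps. Of 29 interferon response genes, 8 were above untransfected cells, 2 below and 19 not called. Isg15 was 3.17 higher (SE 0.49, adjusted p = 0.000162) and Oas2 3.15 higher (SE 0.26, adjusted p = 1.34e-08). Cdh1 was 0.96 higher (SE 0.14, adjusted p = 9.51e-05), Dppa5a 1.60 higher (SE 0.19, adjusted p = 1e-05) and Peg10 3.11 higher (SE 0.20, adjusted p = 1.68e-10). Of 25 matrix genes 17 were higher, and the call of this list ended with an estimated correlation (adjusted p = 0.471). The mesenchymal gene Tnc was at 1.37 (SE 0.11, adjusted p = 1.34e-08). Of 22 glycolysis genes 11 were lower, with Ldha at -0.63 (SE 0.08, adjusted p = 3.04e-05). The call of the glycolysis list ended with an estimated correlation too (adjusted p = 0.471).

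The test called 724 genes, 544 higher and 180 lower, of which 278 changed at least 2-fold and 719 had the same direction in both lines. The count was 87 with DESeq2, 195 with limma and 0 without the line in the model, where 353 genes had an unadjusted p under 0.05. It was 290 without the pre2-2 untransfected library, 167 without the pre2-2 siTet1 library and 1883 without the pre3 untransfected library. Of 71 named genes called, 24 were called without each library.

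Among the most raised were Robo4 (3.49, SE 0.52), Lgals3bp, a secreted glycoprotein (3.09, SE 0.30, adjusted p = 2.07e-07), and Ifi27l1 (3.13), which were called without each library. Raet1c was at least 19.4-fold and Rtp4 at least 9.13-fold higher. Mall (3.66) and the skeletal actin Acta1 (3.32) were higher too, as were Usp18 (24 counts against 2, 13.7-fold, 95% counting interval 3.40 to 120) and Gpr37 (29 counts against 3, with an interval of the ratio of 3.42 to 56.6). The calls of Raet1c, Mall (2.86), Acta1 (1.87), Usp18 and Gpr37 ended without the pre2-2 siTet1 library. Those of Rtp4, Usp18 and Gpr37 ended without the pre2-2 untransfected library. The pre3 untransfected library had no counts of Acta1. Among the most lowered, Uchl1, a neuronal ubiquitin hydrolase, was at -1.53 (SE 0.20, adjusted p = 2.4e-05) and Drp2 at -1.62 (SE 0.23, adjusted p = 5.02e-05), both called without each library, with Drp2 at -1.06 without the pre2-2 untransfected library. Amd1 (-2.91), with shared reads, was also called. Npy2r (-2.74), Kpna7 (-2.32) and Tex19.1 (-1.96) fell as well, with no call without the pre2-2 untransfected library (-2.56, -1.78 and -1.82) or the pre2-2 siTet1 library (-1.65 for Npy2r and -1.75 for Tex19.1), as did Tph1 (-2.50, no call without the pre2-2 siTet1 library).

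Of 25 fibroblast and matrix genes, 17 were higher and none lower (18 and 0 over the list alone), with a median of 0.70, 0.95 in pre2-2 and 0.30 in pre3 (camera adjusted p = 4.34e-15, and adjusted p = 0.471 with an estimated correlation). Of 27 mesenchymal transition genes, 13 were higher and none lower (16 and 0 over the list alone), with a median of 0.74, 0.95 in pre2-2 and 0.22 in pre3 (camera adjusted p = 8.01e-12, and adjusted p = 0.471 with an estimated correlation). Pdgfra, a receptor of mesenchymal cells, was 1.92 higher (SE 0.32), Fbn1 1.08, Col5a1 1.00 and Sparc 0.88 higher, all called without each library. Without the pre2-2 untransfected library Fbn1 was at 0.64, Col5a1 at 0.63 and Sparc at 0.45. Thbs1 (0.96) and Prrx1 (1.03) were not called without that library (0.43 and 0.65), and Vim (0.47) was not called without the pre2-2 siTet1 library (0.37).

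Of 25 mitosis genes, 9 were lower and none higher (19 and 0 over the list alone), with a median of -0.38 (camera adjusted p = 2.51e-14, and adjusted p = 0.471 with an estimated correlation). The calls of Mki67 (-0.50, SE 0.10, adjusted p = 0.00225), Nusap1 (-0.62) and Top2a (-0.44) ended without the pre2-2 siTet1 library (-0.43, -0.60 and -0.38). Of 25 DNA replication genes, 0 were called and 10 were lower over the list alone, with a median of -0.27 (camera adjusted p = 1.63e-06, and adjusted p = 0.471 with an estimated correlation). Of 22 glycolysis and hypoxia genes, 11 were lower and none higher (15 and 1 over the list alone), with a median of -0.36 (camera adjusted p = 5.1e-09, and adjusted p = 0.471 with an estimated correlation); Ldha, Eno1 (-0.57), Pgk1 (-0.60) and the lactate transporter Slc16a3 (-0.87, SE 0.14) were called without each library. Of 20 ATF4 and unfolded protein response genes, 3 were lower, the serine and asparagine synthesis enzymes Psat1 (-0.97, SE 0.12, adjusted p = 1.43e-05), Asns (-0.54) and Phgdh (-0.41), with a median of -0.06 (camera adjusted p = 0.00573, and adjusted p = 0.471 with an estimated correlation). The call of Asns ended without either siTet1 library (-0.66 for pre2-2 and -0.41 for pre3), and that of Phgdh without the pre2-2 siTet1 library (-0.23), the pre2-2 untransfected library (-0.31) or either control siRNA library (-0.42 each).

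The 2 interferon genes called lower were Gbp2 (-1.78) and Iigp1 (1 count against 24). Over the list alone 10 were higher and 2 lower, and the median was 0.30 (camera adjusted p = 0.000219, but 0.128 without the pre3 siTet1 library, and adjusted p = 0.471 with an estimated correlation). Of 6 mesoderm and endoderm genes 4 were higher, Pdgfra, Kdr (1.62), Evx1 (1.51) and Lamb1 (0.65), with a median of 1.13 (camera adjusted p = 3.57e-05, and adjusted p = 0.471 with an estimated correlation). The calls of Kdr, Evx1 and Lamb1 ended without the pre2-2 siTet1 library (1.78, 1.80 and 0.54). Of 7 trophectoderm genes 2 were higher, Rhox6 (2.27) and Peg10 (camera adjusted p = 7.96e-05, but 0.273 without the line, and adjusted p = 0.471 with an estimated correlation). The germline list (camera adjusted p = 0.00502, and adjusted p = 0.471 with an estimated correlation) had 1 gene lower over all genes, Tex19.1, and 2 over the list alone. Of 18 imprinted genes 3 were higher, Igf2 (0.97), Dlk1 (1.48) and Igf2r (0.60), the last 2 with no call without the pre2-2 siTet1 library (1.59 and 0.45). BMP targets (0 of 14 called) and imprinted genes each had a camera adjusted p of 0.0494, which became 0.471 with an estimated correlation and 0.055 with library totals alone. Without the line the values were 0.0926 and 0.273. BMP targets also lost their call without the pre2-2 untransfected (0.537), pre2-2 siTet1 (0.113) or pre3 siTet1 library (0.0752). Imprinted genes lost it without any library but the pre3 untransfected (0.0611 to 0.176).

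Other lists were not called for siTet1 against untransfected. In the pluripotency list (camera adjusted p = 0.254) 4 genes were higher, Dppa5a, Dppa2 (1.58), Klf5 (0.75) and Tdgf1 (0.39), and 2 lower, among them Nr0b1 (-0.93). In the epithelial list (0.0676) 3 were higher, Cdh1, the P-cadherin gene Cdh3 (2.64) and Perp (0.35). The DNA methylation list (0.304; median 0.00, mean -0.01) held 2 lower genes, Idh2 (-0.62) and Uhrf1 (-0.37), and the jumonji list (0.254) held Jhdm1d (-0.65). Smad7 (0.86) and Tdgf1 were higher in the Nodal list (0.183). In the neural list (0.669; median -0.02, mean 0.16) Gbx2 (1.74) and Nes (0.75) were higher and Stmn2 (-0.38) lower. Single called genes were Cdkn2b (1.01) in the p53 list (0.863), Pecam1 (-1.18) in the haematopoietic and endothelial list (0.418; median 0.05, mean -0.09) and Acta1 in the muscle and fat list (0.0676). The hydroxylase (0.671), Hox (0.813; median -0.01, mean 0.11) and cholesterol lists (0.285) held no called gene. The pluripotency list gained a call without the pre2-2 untransfected library (0.0254), the epithelial list without the pre2-2 siTet1 library (0.0423), and the muscle and fat list without the pre3 untransfected (0.0279) or siTet1 library (0.00333), each in the direction of the main test. Of the genes named here, Cdh1, Dppa5a and Cdh3 were called without each library. Idh2 was not called without the pre3 untransfected (-0.43) or siTet1 library (-0.51), and the others were not called without the pre2-2 siTet1 library. There Dppa2 was at 1.76, Klf5 0.70, Tdgf1 0.19, Nr0b1 -0.28, Perp 0.32, Uhrf1 -0.26 and Jhdm1d -0.69. Smad7 was at 0.68, Gbx2 1.33, Nes 0.53, Stmn2 -0.33, Cdkn2b 0.97, Pecam1 -1.11 and Acta1 1.87.

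The comparison of pre3 with pre2-2 described the 2 lines across treatments. The 3 libraries of a line are its 3 treatments, and the labels do not say whether they were grown separately. The p-values here rest on the spread between these libraries, not between independently derived lines. Pou5f1, the pluripotency factor, was 2.45 higher in pre3 (SE 0.06, adjusted p = 6.69e-20), at 5794 to 6619 CPM against 1042 to 1208 in pre2-2. The counts do not separate transcripts of a Pou5f1 transgene, if the lines carry one, from those of the gene itself. Gdf3, a growth factor of pluripotent cells, was 2.56 higher in pre3 (SE 0.17). Of 25 fibroblast and matrix genes 22 were lower in pre3 and 1 higher, with Tagln at -2.96 (SE 0.15, adjusted p = 9.72e-14), and of 29 interferon genes 24 were lower, with Irgm1 at -3.50. Of 22 glycolysis and hypoxia genes 19 were higher, with Ndrg1 at 2.11 (SE 0.11, adjusted p = 2.62e-13), and the calls of these 3 lists ended with an estimated correlation (adjusted p = 0.477).

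The test called 3335 genes, 1586 higher and 1749 lower in pre3 (3 libraries per line), of which 1136 changed at least 2-fold and 3256 had the same direction in all 3 treatments. The count was 1429 with DESeq2, 2061 without the treatment in the model, and 2172 and 2173 without the control siRNA library of pre2-2 and of pre3. Of 106 named genes called, 98 were called without each library.

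Among the genes highest in pre3 over pre2-2, the axonemal dynein gene Dnahc2 (205 counts against 1; 24.5 to 47.2 CPM in pre3 and 0 to 0.389 in pre2-2) was 239-fold higher (95% counting interval 42.4 to 9484). Chadl (52 against 1) was 60.6-fold higher (10.4 to 2440), and Nos2 had 77 counts against 2. Of transcription factors, Dmrta2 (40 against 1) was 46.6-fold higher (7.90 to 1887), Sox1 (39 against 2) 22.7-fold (5.88 to 194), and Barx1 was at 5.08. Avil, with no counts in pre2-2, was at least 26.0-fold higher. Among the lowest, the glycosyltransferase gene Mgat4c (1 count against 453) was 389-fold lower (69.4 to 15383) and the endothelial receptor Tie1 (1 against 62) 53.2-fold (9.20 to 2134). Atoh8 was at least 11.2-fold, Gbp1 at least 8.58-fold and Prl2c3, which shares 60.0% of its words with Prl2c2, at least 14.6-fold lower.

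Fibroblast and matrix genes were lower in pre3 in 22 of 25 cases and higher in 1 (the same counts over the list alone), with a median of -1.50 (camera adjusted p = 5.49e-27, and adjusted p = 0.477 with an estimated correlation), among them Acta2 (-2.75), Bgn (-1.81) and Sparc (-1.76). Mesenchymal transition genes were lower in 21 of 27 and higher in 1 (23 and 1 over the list alone), with a median of -0.95 (camera adjusted p = 1.19e-16, and adjusted p = 0.477 with an estimated correlation), among them Thbs1 (-2.81) and Tnc (-2.38). Interferon genes were lower in 24 of 29 and higher in none (27 and 1 over the list alone), with a median of -1.65 (camera adjusted p = 3.56e-15, and adjusted p = 0.477 with an estimated correlation), among them Oasl2 (-3.03) and Irf7 (-2.59).

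Glycolysis and hypoxia genes were higher in pre3 in 19 of 22 and lower in none, also over the list alone (median 0.64, camera adjusted p = 2.63e-18, and adjusted p = 0.477 with an estimated correlation), with Slc16a3 at 1.58, Tpi1 at 1.00 and Ldha at 0.77. Cholesterol synthesis genes were higher in 10 of 19 (11 over the list alone; median 0.48, camera adjusted p = 0.000721, and adjusted p = 0.494 with an estimated correlation), with Insig1 at 1.07. Mitosis genes were higher in 12 of 25 (16 over the list alone; median 0.31, camera adjusted p = 0.000546, and adjusted p = 0.662 with an estimated correlation), with Top2a at 0.51 and Mki67 at 0.48. Pluripotency genes went both ways, with 10 of 24 higher and 8 lower (11 and 8 over the list alone; median 0.21, camera adjusted p = 0.0101, and adjusted p = 0.477 with an estimated correlation), Dppa5a at 1.77 and Fgf4 at -0.95. Epithelial genes were lower in 10 of 20 and higher in 4 (11 and 5 over the list alone; median -0.49, camera adjusted p = 0.0484, and adjusted p = 0.477 with an estimated correlation), with Krt8 at -1.47, Epcam at -1.24 and Cdh1 at -1.11. The epithelial call ended with library totals alone (0.055) and without the control siRNA library of pre2-2 (0.118) or pre3 (0.117) or the pre2-2 siTet1 library (0.0501).

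Of 18 imprinted genes 1 was higher and 7 lower in pre3 (median -0.31, camera adjusted p = 0.00425, and adjusted p = 0.477 with an estimated correlation), with Mest at -1.55 and Igf2 at -1.29. Of 6 mesoderm and endoderm genes 1 was higher and 4 lower (0.00425, and adjusted p = 0.477 with an estimated correlation), with Kdr at -3.19. Of 20 p53 genes 7 were higher and 2 lower (0.0156, and adjusted p = 0.477 with an estimated correlation), with Bbc3 at 1.42; the list was not called without the untransfected library of pre2-2 (0.0618) or pre3 (0.0623). Of 14 BMP targets 2 were higher and 6 lower (0.0266, and adjusted p = 0.519 with an estimated correlation), with Bmp7 at 2.86; the list was not called without the control siRNA library of pre2-2 (0.102) or pre3 (0.0964). The remaining lists were not called, though they held genes called higher and lower. These were 7 and 3 for DNA methylation (0.0954), with Idh2 at 1.33, 3 and 3 for jumonji (0.543), and 6 and 4 for hydroxylases (0.196), with Egln3 at 1.62. Trophectoderm genes had 2 and 2 (0.211; median 0.01, mean -0.21), with Rhox6 at 3.48 and Peg10 at -4.34, and Nodal genes 3 and 4 (0.627; median 0.13, mean -0.01), with Fst at -3.73. Neural genes had 4 and 3 (0.730; median -0.26, mean 0.27), with Otx2 at 1.82 and Tubb3 at -2.73. Hox genes had 4 and 2 (0.510; median -0.04, mean 0.16), with Hoxd9 at 2.87 and Hoxb9 at -2.23. DNA replication had 5 and 0 (0.0954), ATF4 7 and 2 (0.167), haematopoietic and endothelial genes 1 and 4 (0.210), with Tek at -1.34, muscle and fat 0 and 1 (0.510), and germline 0 and 0 (0.753). DNA replication gained a call without the untransfected library of pre2-2 (0.00475) or pre3 (0.0045), and hydroxylases without the siTet1 library of pre2-2 (0.0424) or pre3 (0.0428).

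Whether the effect of siTet1 differed between the lines was tested as an interaction of line with siTet1 or not, with the control siRNA and untransfected libraries of a line pooled as its 2 controls. A change between these 2 controls therefore adds to the spread, and the test is not one of siTet1 against control siRNA alone. EdgeR called 0 genes, with 270 of 11048 at an unadjusted p under 0.05, where 552.4 would be expected by chance. DESeq2 and limma called 0 as well, DESeq2 with 19 genes at an unadjusted p under 0.05. The lowest p, none of them called, belonged to the adhesion gene Ceacam1 (-1.75, SE 0.35, pre3 minus pre2-2), the transcription factor gene Tcfap2c (1.75, SE 0.40), the phosphatase gene Dusp5 (-1.35, SE 0.31), Gm3696, which shares 67.4% of its words with Gm2897, and the photoreceptor cadherin gene Cdhr1 (-1.08, SE 0.26). Of these, Ceacam1 shares 29.6% of its words with Ceacam2. Without a filter 7 genes were called, and without the pre2-2 control siRNA library 4. The median SE was 0.357, against 0.202 for siTet1 against control siRNA. In simulated data with no difference between the 2 controls, 22.4% of 2-fold differences between lines were recovered, so differences of that size were mostly not detectable with these libraries.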

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

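All tests of explanations in this part were chosen only after the result was seen, except the count of splits for the difference between lines; the comparison of transfected with untransfected cells between lines was also added after the data were seen.

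Of 29 interferon response genes, 16 were called higher with control siRNA than with siTet1, with a list median for siTet1 minus control siRNA of -1.50 in pre2-2 and -0.43 in pre3, and the call of the list ended with an estimated correlation (adjusted p = 0.441). A weaker transfection of the siTet1 libraries that lowers every transfection response in like proportion would lower genes outside the list too. Those that control siRNA raised in pre2-2 had a median of 0.121 in pre3 (95% bootstrap interval 0.0112 to 0.176, 476 genes), where a fall to -0.0915 was needed. Those it raised in pre3 had a median of -0.0957 in pre2-2 (-0.256 to 0.0284, 144 genes), where -0.504 was needed. The falls needed were not seen, but the test cannot decide. The untransfected pre2-2 library either chose the genes or set the fall needed, and a state of that culture stays open below. An effect of Tet1 reduction on these genes could also hide a fall. A control siRNA that stimulates the interferon genes more than the Tet1 siRNA stays open as well. Of the 16 members lower with siTet1 than with control siRNA, 2 were called below untransfected cells (Gbp2 and Iigp1), 5 above, and 9 were not called. An effect of Tet1 reduction itself also stays open, as the series has a single Tet1 siRNA treatment.

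Of 25 fibroblast and matrix genes, 13 were called higher with control siRNA than in untransfected cells, with a list median of 1.06 in pre2-2 and 0.127 in pre3, and the call of the list ended with an estimated correlation (adjusted p = 0.552). The difference between lines is given below with its own tests. Pre3 cells in the untransfected pre2-2 library could lower these genes there, but 6 genes seen in pre3 and near 0 in transfected pre2-2 reached 1.43% (0.381 to 2.87) of their pre3 level, where 74.5% was needed, which argues against it. A state of the untransfected pre2-2 culture could give the larger rise in pre2-2 and stays open, since the list moved by 0.127 in pre3. The list kept its direction and call without that library, so such a state need not account for the whole call. That library lay apart from the others of its line on the first principal component (-19.0 against -41.5 and -41.2). So did the untransfected library of pre3, in the same direction (43.4 against 32.2 and 26.1). A difference of the lines in their response would also give the larger rise in pre2-2. With 1 library per line and treatment these explanations cannot be told apart.

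Amd1, Gm4535 and Rangrf were at 0 in some libraries and abundant in others. The values that shared reads would need were there: summed counts of Amd1 and Amd2 changed by -0.0714, and those of Rangrf and Gm4535 by -0.247, for control siRNA against untransfected, so the switches may lie in how reads were divided between near-identical genes. No biological explanation was tested.

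The 3335 genes called between lines came from 1 of the 10 splits of the 6 libraries into 3 and 3; the highest of the other splits called 0. With 10 splits a share under 0.05 cannot be reached.

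The lines differed in the effect of siTet1, against the pooled control siRNA and untransfected libraries, in 6 gene lists by camera on the interaction, given as median log2 difference, pre3 minus pre2-2: interferon 0.608 (adjusted p = 0.00266), mesenchymal transition -0.279 (adjusted p = 0.00266), collagen and HIF hydroxylases -0.385 (adjusted p = 0.00144), mitosis 0.152 (adjusted p = 0.00345), DNA replication 0.177 (adjusted p = 0.00608) and glycolysis and hypoxia -0.258 (adjusted p = 0.00345). With an estimated correlation each had an adjusted p of 0.947. Since the 2 kinds of control are pooled, the response to transfection enters these differences. For siTet1 against control siRNA alone, the medians in pre2-2 and pre3 were -1.50 and -0.43 for interferon, 0.10 and 0.14 for mesenchymal transition, 0.11 and -0.02 for collagen and HIF hydroxylases, -0.27 and -0.24 for mitosis, -0.16 and -0.12 for DNA replication and -0.08 and -0.13 for glycolysis and hypoxia genes. All but that of interferon differ by less than the values above, and that of mesenchymal transition differs in the opposite direction. These differences were not tested. In the interaction 0 single genes were called by edgeR (270 at an unadjusted p under 0.05; DESeq2 and limma 0).

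For transfected against untransfected cells, 6 lists differed between lines by the same test: mesenchymal transition -0.710 (adjusted p = 3.12e-11, and adjusted p = 0.379 with an estimated correlation), fibroblast and matrix -0.691 (7e-12, and adjusted p = 0.543 with an estimated correlation), DNA replication 0.322 (3.43e-05), mitosis 0.262 (3.6e-05), glycolysis and hypoxia -0.260 (0.0317) and collagen and HIF hydroxylases -0.254 (0.0494), the last 4 with an adjusted p of 0.850 with an estimated correlation. Here the control siRNA and siTet1 libraries of a line were pooled as transfected. The model assumes that these vary like replicates, although 175 genes were called between siTet1 and control siRNA. Each line has 1 untransfected library, and both lay apart from their lines on the first principal component, in the same direction. A difference between lines therefore cannot be told from a state of 1 of these cultures. The single gene called was Amd2, at -8.33 (adjusted p = 0.000349), which shares reads with Amd1; DESeq2 called 5 genes and limma 1, and 603 had an unadjusted p under 0.05 with edgeR. The call of Amd2 was lost without the pre2-2 control siRNA or siTet1 library, where 0 genes were called.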

How the results depend on the processing

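The number of genes called for siTet1 against control siRNA, 175, became 89 at a log2 change of at least 1, 292 without a filter, 24 with DESeq2, 33 with limma, 0 with no replicate block (178 genes at an unadjusted p under 0.05), 614 with only the 4 libraries compared and the line as replicate block, 114 with both control groups pooled, and 32 to 625 leaving out each library. The change of Tet1 kept its sign in every setting and lost its call with DESeq2 (-0.67), limma (-0.64) and no replicate block (-0.67); leaving out each library gave -0.76 to -0.58. For control siRNA against untransfected, 164 became 259 without a filter, 32 with DESeq2, 32 with limma, 0 with no replicate block (84 at an unadjusted p under 0.05) and 29 to 713 leaving out each library. For siTet1 against untransfected, 724 became 278 at a log2 change of at least 1, 87 with DESeq2, 195 with limma, 0 with no replicate block (353 at an unadjusted p under 0.05) and 167 to 1883 leaving out each library. For the lines, 3335 became 1136 at a log2 change of at least 1, 1429 with DESeq2, 2061 without a treatment term and 2172 to 3538 leaving out each library. The line-dependent siTet1 effect, 0 genes with edgeR (270 at an unadjusted p under 0.05), gave 7 without a filter, 0 to 4 leaving out each library and 0 with DESeq2 and limma; it could not be fitted without either siTet1 library, nor the line-dependent transfection effect without either untransfected library. The between-line r of 0.339 was 0.374 among genes with an average log2 CPM of at least 3. Settings with fewer libraries have fewer degrees of freedom; otherwise the cause of these changes was not tested. Results that turned to the opposite sign, with their range leaving out each library, were as follows, and the cause was not tested. For siTet1 against control siRNA, Acta1 ranged from -0.12 (without control siRNA replicate 1) to 2.37 and Irgm2 from -2.51 to 0.15 (without siTet1 replicate 1). The fibroblast and matrix list there had adjusted p from 0.00051 to 0.854 and was lower without control siRNA replicate 2 (0.00366). For control siRNA against untransfected, the mitosis list had adjusted p from 1.07e-07 to 0.958 and the DNA replication list from 3.23e-06 to 0.869, both highest, with the other sign, without untransfected replicate 1. Of 5384 results of named genes under all alternatives, 4682 kept direction and side of the threshold, 584 lost their call, 116 gained one and 2 reversed. Of 840 list results these were 723, 84, 30 and 3. Those that kept include results called in neither setting. With an estimated correlation every list result called in the main test, 40 of 96, lost its call. That form rests on 2 residual degrees of freedom, so a lost call does not show that correlated genes were the reason. Trophectoderm genes, at an estimated correlation of -0.143 for siTet1 against control siRNA, went from a camera p of 2.7e-07 to 0.0338. At 1868640 to 2582800 counts per library, a gene under 1.16 to 1.61 CPM lies under the floor of 3 counts, and 1.5-fold changes were mostly missed in simulated data (32.8% recovered for siTet1 against control siRNA).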

Other observations

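The genes of this paragraph were looked at after their values were seen, and no explanation was tested. Lars2, the mitochondrial leucyl-tRNA synthetase, rose from 170 to 460 to 990 CPM from untransfected to control siRNA to siTet1 in pre2-2 and from 350 to 556 to 903 in pre3; siTet1 was 0.92 above control siRNA (SE 0.15, adjusted p = 0.00089), control siRNA 1.01 above untransfected, and siTet1 1.93 above untransfected. Pou5f1 was at 1042 to 6619 CPM in every library while Nanog did not exceed 3.61 CPM; the files do not separate transcripts of a Pou5f1 transgene, if the lines carry one, from those of the gene itself.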
